A study of Drosophila melanogaster with 3 samples.

How the data were processed

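Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster animals at the white prepupa stage, with males and females pooled. Per the labels, the animals were transgenic flies in which CG8632, the gene named ZnT49B in the annotation used here, was expressed as a fusion with enhanced green fluorescent protein (eGFP). The immunoprecipitation used an antibody against GFP. Chromatin was sheared by sonication to a labelled size range of 200 to 800 bp. The series held 3 samples, which the labels number as biological replicates 1 to 3 of 1 group, so no comparison between conditions was possible. Control samples were not analysed here.

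The deposited files were peak lists, each made on genome builds dm3 and dm6. Each replicate had a relaxed list of peaks and background calls meant as input for an irreproducible discovery rate (IDR) analysis. The series also had a relaxed list called on the replicates pooled and a set of optimal IDR-thresholded peaks, called the IDR set in the text. Each interval carried a signal value from the authors' peak caller, used as deposited to rank calls within a list. Signal values are also given as medians of a list and as mean ± SD over the replicates, and since its scaling between libraries is unknown, that SD may include differences in scale. Each interval also carried a significance column on the −log10 scale, deposited with the signal and used only to describe the lists. The peak caller, its cut-off, the control correction, the aligner, the treatment of reads that match several places and the IDR threshold are not given in the sources used here. Read depth is likewise not given there, so the depth behind a peak is unknown and no read-based error could be attached to a signal value. The relaxed lists of replicates 1 and 3 and of the pooled reads each held 30000 calls and that of replicate 2 held 29322. Because the relaxed lists include background calls on purpose, most comparisons of replicates used their strongest 6469 calls, the number in the IDR set. Calls of every rank were used for the TSS share by rank, the signal in each replicate, the correlation of signals, the tagged gene and where the text says any rank or the last calls. All 6469 IDR peaks were identical to the 6469 strongest calls of the pooled list, so the set is a cut of that list by signal and has no replicates of its own. Values from the separate replicate lists are therefore given beside it as mean ± SD (n = 3).

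Positions were taken from the dm6 files and compared with the Release 6 genome sequence and the Ensembl release 115 gene annotation, without transposable elements (18358 genes). The dm3 files were used only for counts, overlaps and signal, since no dm3 annotation was used here. Coordinates are 1-based. A peak was counted at a transcription start site (TSS) when its summit lay within 500 bp of the start of any annotated transcript. Random expectation came from 1000 placements of the same peaks on the same chromosomes outside unsequenced bases, or 100 placements for the overlap of replicates. A summit was assigned to 1 feature, with coding exon taken before 5′ UTR, 3′ UTR, non-coding exon, intron and intergenic sequence. Shares of peaks or genes have Wilson 95% intervals, which cover counting error only.

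Genes with an IDR peak at a TSS were counted in 25 lists. Each list was compared with all other protein-coding genes, or with all other non-coding genes for the lists of non-coding genes, by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the lists. Of 331 list entries, 11 matched no gene and were not used. Sequence content was taken from windows reaching 100 bp to either side of summits and scored for 16 consensus sequences on both strands. The control windows lay 1000 bp to either side and overlapped no IDR peak. Windows drawn at random and matched on GC content in steps of 1% were the alternative control. Signal at a TSS and elsewhere was compared by a two-sided permutation test with 100000 resamples, and chromosomes by exact binomial tests against their share of TSS positions. These tests treat peaks or genes as independent units. They do not measure variation between animals, for which the spread of the 3 replicates is given.

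The groups, tests, gene lists, consensus sequences, alternatives and the rule for naming genes were fixed before the data were examined. Genes are named when they belong to the 15 strongest IDR peaks (every gene with a TSS within 500 bp of the summit, otherwise the gene holding the summit, otherwise the nearest gene) or are the tagged gene. They are also named as the 3 members of each list with the strongest IDR peak at a TSS (6 for the zinc and ecdysone lists), as the first 2 members in alphabetical order of lists with none, and as the 3 genes whose bodies hold the most IDR peaks. Some genes that this rule selects are not used here. Other names in the text were chosen after their values were seen, and the text says so. Alternatives covered the TSS window (250 and 1000 bp), the number of calls compared, the overlap that counts as shared, the peak set, the TSS definition, the control windows and their size, the build, and leaving out each replicate. For the last, the IDR set was replaced by the strongest calls of 1 remaining replicate that overlap the strongest calls of the other. These sets held 5040 to 5130 peaks against 6469 in the IDR set, so shares of genes with a peak can fall for that reason alone.

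The computations were tested on simulated data. With 30% of 6469 simulated peaks planted at TSSs, 39.6% lay at a TSS against 13.6% after random placement, and 0 of 100 placements were as high. The difference as a percent of the peaks not at a TSS by random placement, which estimates the planted share, was 30.1%. In a first set with none planted, 2 of 100 placements were as high as the set. Because of that outcome 20 further such sets were added, and 0 of 20 passed a p of 0.05. A list planted at 60% among genes at a lower share was called in 50 of 50 simulations over 18277 genes, with 6 calls among 1200 tests of other lists. With no list planted there were 3 calls among 1200 tests. A consensus planted in 10% of windows was the 1 called of 16. Both sets of windows in that simulation were drawn at random from the genome. It therefore did not cover the difference in GC content between real summits (34.3%) and their control windows (41.9%). Intervals shared at 70% gave an overlap of 71.1%. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.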

Results

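The assay mapped where DNA was recovered with an antibody against GFP in whole white prepupae that expressed the CG8632-eGFP fusion protein. At this stage the larva has just formed its puparium. Whether the recovery depended on the fusion protein could not be tested, since control samples were not analysed here. CG8632 is ZnT49B, by its name a member of the ZnT family, whose proteins are membrane transporters of zinc. The data were 3 biological replicates of 1 group, and the question addressed was which sites and genes carried peaks in all of them. The IDR set held 6469 peaks in 6072 separate regions, which covered 2475 kb or 1.81% of the sequenced bases of the main chromosomes. The median signal of the relaxed lists was 20.01 in replicate 1, 14.9 in replicate 2 and 20.6 in replicate 3. Calls with a significance value over 2 on the −log10 scale made up 32.5%, 15.4% and 27.6% of them.

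The strongest IDR peak lay in an intron of CG11050 (FBgn0031836) on chromosome 2L (dm6, 6612461 to 6612914), with a signal of 975 ± 174 over the replicates (SD, n = 3) and a rank of 1 to 3 in each. The next was an intergenic peak at the promoter of Ugalt (FBgn0024994; X, 2703694 to 2704077), which encodes a UDP-galactose transporter, with 964 ± 70.7. The peak ranked 3 lay in an intron of ush (FBgn0003963; 2L, 480875 to 481297), which encodes a cofactor of GATA transcription factors, with 912 ± 240. Rank 4 was at the promoter of CG14100 (FBgn0036889; 3L, 19590427 to 19590806), with 919 ± 32.3. Rank 5 (2R, 13035132 to 13035536) was intergenic, and its nearest TSS, that of CG13323, was 11914 bp away. Among the 10 that followed, the TSS peaks were those of CG18549, PNPase (a mitochondrial RNA-degrading enzyme), the divergent pair mRpS23 and CenG1A, larp (an RNA-binding protein), the divergent pair Pex11ab and CG8320, and the divergent pair Chro (a chromatin protein) and Ssl1 (a subunit of the general factor TFIIH). The others lay in introns of Lk6 (a protein kinase) and CG32772, in the lncRNA:CR46035 exon inside osa (a subunit of a chromatin remodelling complex), and nearest to CG31668, 3770 bp from its TSS. In every replicate each of these 15 peaks had a rank of 23 or better.

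Peaks were concentrated at promoters and in introns and were nearly absent from coding exons. Summits of 2278 IDR peaks, or 35.2% (Wilson 95% interval 34.1 to 36.4), lay within 500 bp of a TSS, against 13.6% of randomly placed peaks. The excess was 2.60-fold, with a one-sided p of 0.001, the smallest that 1000 placements can give. The strongest 6469 calls of the replicates gave 36.0% ± 2.05 (SD, n = 3). Where a summit was at a TSS, it was usually just upstream, at a median of −131 bp (quartiles −245 and −23), and 78.0% of these summits were upstream. Introns held 56.1% of summits against 42.7% at random, and intergenic sequence 34.3% against 30.5%. The 5′ UTRs held 5.39% against 3.06%. Coding exons held 28 summits, or 0.433%, against 17.0% at random, and the replicates gave 0.4998% ± 0.172 (SD, n = 3). The 3′ UTRs were also under their random share, at 1.30% against 4.95%. Each of these shares lay outside the range of the 1000 placements, with a two-sided p of 0.002, the smallest they can give. Peaks at a TSS had a median signal of 207.5 and the others 180.9, a ratio of 1.15 with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. The ratio was 1.17 ± 0.0793 over the replicates (SD, n = 3).

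**Figure D1:**
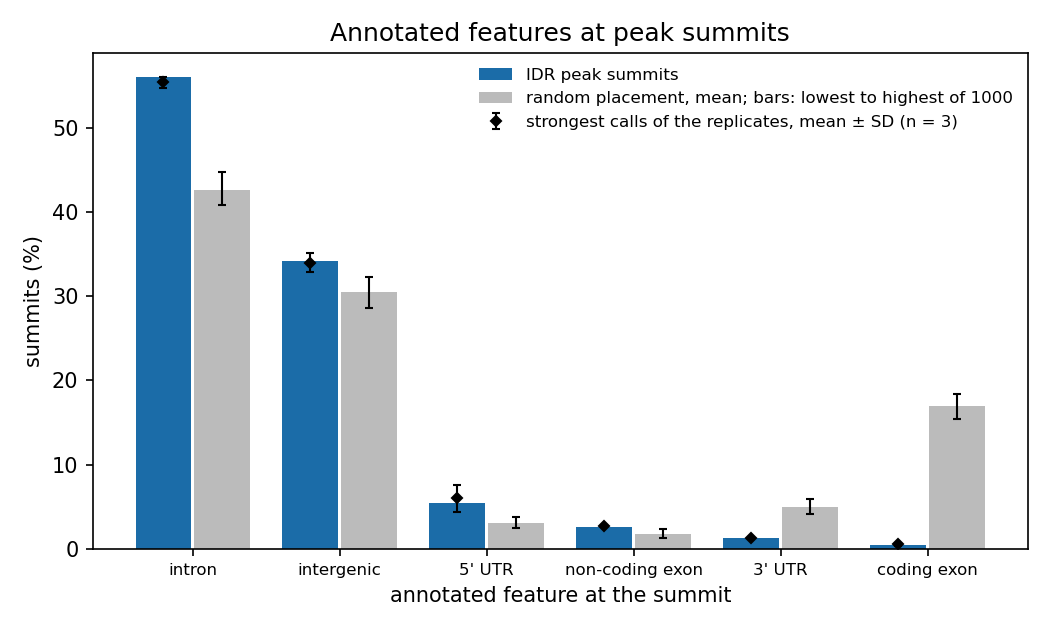
Percent of IDR peak summits in each annotated feature (blue) and the mean of 1000 random placements (grey, with their lowest and highest values). Diamonds are the strongest calls of the 3 replicates, mean ± SD. Coding exons held 0.433% of summits against 17.0% at random, and introns 56.1% against 42.7%.

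The share of calls at a TSS fell with rank in every replicate. Among the 1000 strongest calls it was 46.7% ± 1.33 (SD, n = 3), and in the calls ranked 28001 to 29000 it was 15.9% ± 1.81, close to the 13.6% of random placement. The difference of 30.8 ± 2.42 percentage points ranged from 28.0 to 32.5 over the replicates. With 3 paired differences an exact test cannot go below p = 0.25, so none was run.

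**Figure D2:**
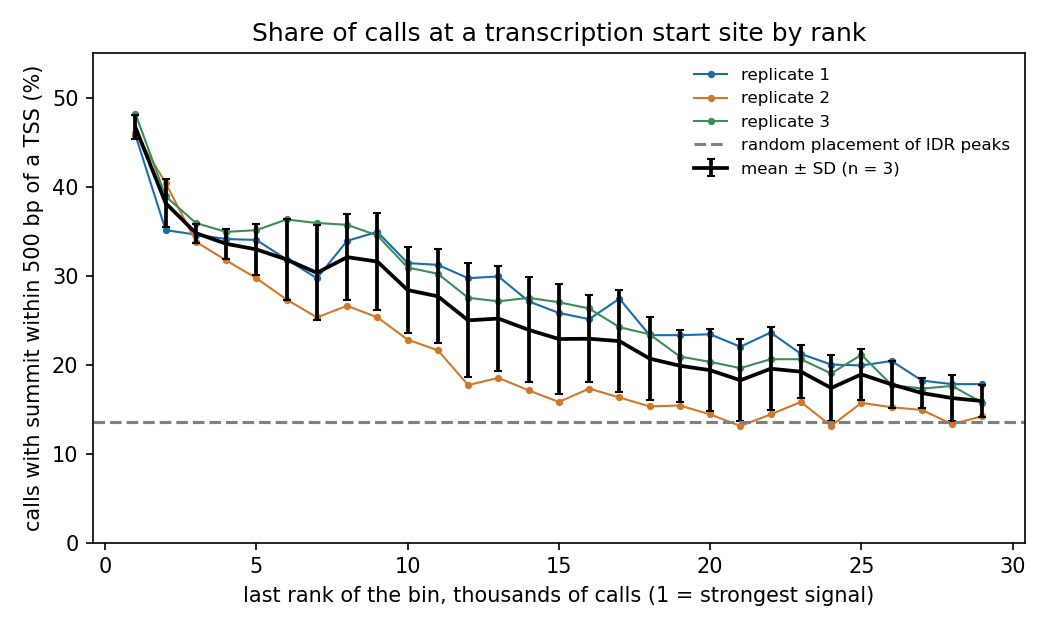
Percent of calls with the summit within 500 bp of a TSS (vertical axis) in bins of 1000 calls ordered by signal (horizontal axis). Colours are the 3 replicates, black is their mean ± SD, and the dashed line is the 13.6% of randomly placed IDR peaks. The mean falls from 46.7% to 15.9%.

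An IDR peak lay at the TSS of 2373 protein-coding genes, or 17.0%. Of the 25 gene lists, 2 had peaks at more of their members than other genes of the same class, 4 at fewer, and 19 did not pass the test. Cytoplasmic ribosomal protein genes were highest, with a peak at 57 of 93, or 61.3%, against 16.7% of other protein-coding genes (Fisher exact, adjusted p = 2.31e-20). Among them were peaks at RpS27 (504.0 in the pooled signal) and RpL34b (447.8), the latter shared with the neighbouring CG8132. The replicates differed for this list, at 44.1% in replicate 1, 55.9% in replicate 2 and 72.0% in replicate 3. It passed the test with each left out, and without replicate 3 the share was 40.9%.

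The ecdysone response list, genes of the steroid pulse that starts metamorphosis, had a peak at 14 of 31 members, or 45.2%, against 16.9% (exact test, adjusted p = 0.00118), and at 48.4% in each replicate. Its strongest peaks were at E23, an ecdysone-induced transporter (2L, 3354916 to 3355295; rank 82 in the IDR set, signal 392 ± 109 over the replicates, SD, n = 3), bun (rank 298, 253 ± 16.3), the nuclear receptor genes Eip75B (rank 407, 219 ± 81.8) and Hr78 (rank 606, 188 ± 63.6), the repressor gene vri (rank 1700, 98.9 ± 35.3), and tai, a coactivator of the ecdysone receptor (rank 1744, 97.2 ± 10.3). The tai summit was nearer to the TSS of CG9586. The list did not pass when only the outermost start of each gene was used (22.6%, exact test, adjusted p = 0.352). Any annotated start of a gene counted in the main test. Other genes were not matched to the list on number of starts or on length (median 22.3 kb in the list). A larger number of starts per gene may therefore contribute to the excess.

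The lists with fewer peaks were cuticle proteins, with a peak at 1 of 120 (Cpr12A), odorant and gustatory receptors, with 1 of 120 (Gr77a), replication-dependent histones, with 0 of 112, and digestive enzymes, with 1 of 44 (Mal-A5). Of other protein-coding genes, 17.0% to 17.1% had one. The adjusted p was 6.46e-08 for cuticle proteins and for the receptors, 1.48e-08 for histones and 0.0180 for digestive enzymes. The cuticle list fell to 0 without replicate 1 or 2 and the receptor list without replicate 1 or 3, and both still passed. The histone genes, such as His1:CG31617 and His1:CG33801, are near-identical copies, so their reads are shared and absence of a peak is uncertain. The histone list stayed at 0 but did not pass among genes with no other gene's TSS within 500 bp (exact test, adjusted p = 0.467). The digestive enzyme list did not pass in 7 of its 8 alternatives, among them leaving out any 1 replicate. Its share stayed at 2.27% with each replicate left out, in sets of 5040 to 5130 peaks against 6469. The lost call there therefore does not show that the low share depends on a replicate. Its single peak, at Mal-A5, was strong, at rank 148 with 323 ± 60.1.

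**Figure D3:**
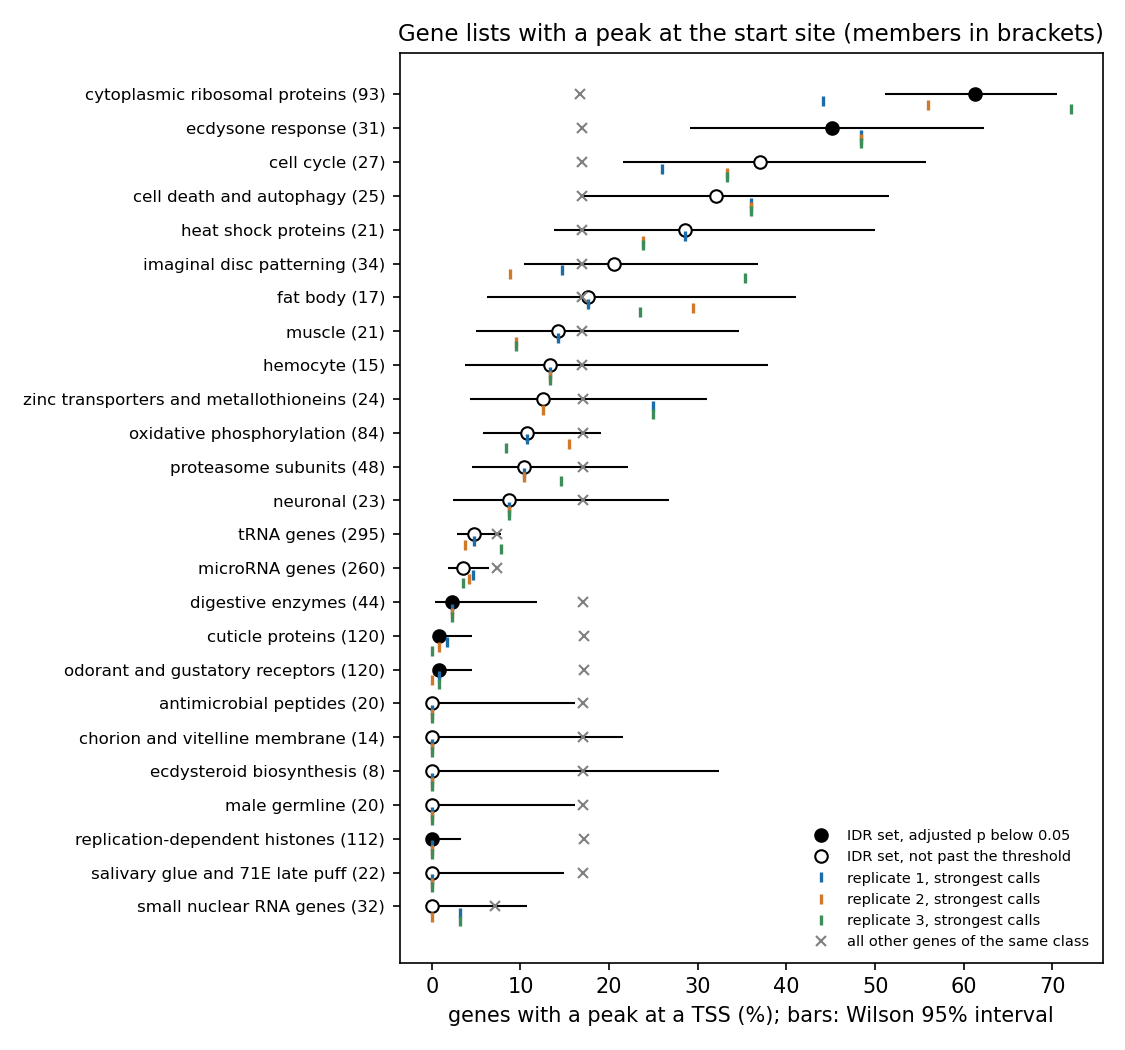
Percent of the genes of each list with an IDR peak within 500 bp of a TSS (horizontal axis), with Wilson 95% intervals. Filled circles passed the test, ticks are the strongest calls of each replicate and crosses are the other genes of the same class. Ribosomal protein genes lie at 61.3% and the ecdysone response list at 45.2%, while cuticle proteins and receptors lie at 0.833%.

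Single members of lists that did not pass carried strong peaks. Hsp27 (3L, 9383707 to 9384095) had rank 20 (631 ± 116 over the replicates, SD, n = 3), Hsp26 rank 339 and Hsc70-5 rank 471 in the heat shock list (6 of 21, exact test, adjusted p = 0.238). In the cell death and autophagy list (8 of 25, exact test, adjusted p = 0.122), the death gene hid had rank 255, Atg17 rank 675 and Atg18a rank 1944. Without replicate 3 this list passed (36%, exact test, adjusted p = 0.0245). The cell cycle list had 10 of 27 (exact test, adjusted p = 0.0539), led by Dp, CycE and Mcm2, and the imaginal disc list 7 of 34 (adjusted p = 0.596), led by Dll, so and dac. The replicates gave 14.7%, 8.82% and 35.3% for the imaginal disc list, and with 1 left out it had 5.88% to 8.82%. The cell cycle list passed with a TSS window of 1000 bp (44.4%, exact test, adjusted p = 0.0202) but fell to 22.2% without replicate 2 (adjusted p = 0.390) or replicate 3 (adjusted p = 0.349), and to 21.4% among genes with no other gene's TSS within 500 bp. The neuronal list had 2 of 23 (exact test, adjusted p = 0.511), elav at rank 197 and comt at rank 2649, and the elav summit was as near to lncRNA:enrr. The summits counted for Rpn5, ND-42, ND-MWFE, Mcm2, Atg17, bmm, PPO3 and tRNA:Tyr-GTA-1-8 were nearer to the TSS of another gene. Muscle had 3 of 21 (Tm1, sls, Act87E; exact test, adjusted p = 1), fat body 3 of 17 (bmm, Adh, mdy; adjusted p = 1) and hemocyte 2 of 15 (PPO3, ush; adjusted p = 1). Without replicate 1 the muscle list fell from 14.3% to 4.76% and the hemocyte list from 13.3% to 6.67%. Both lists are short and that set held 5040 peaks against 6469, so these falls need not come from replicate 1. Proteasome subunits had 5 of 48 (Rpn3, Rpn5, Rpn11; exact test, adjusted p = 0.463) and oxidative phosphorylation 9 of 84 (ND-ASHI, ND-42, ND-MWFE; adjusted p = 0.238). Without replicate 2 the oxidative phosphorylation list passed as lower (4.76%, exact test, adjusted p = 0.0318), and it was at 5.95% without replicate 1 and 7.14% without replicate 3. The proteasome list fell from 10.4% to 6.25% without replicate 3. No IDR peak was at a TSS of the ecdysteroid biosynthesis list (8 genes, such as Ptth and dib; exact test, adjusted p = 0.482), the salivary glue and late puff list (22, such as Eig71Ea and Eig71Eb; 0.0905), antimicrobial peptides (20, such as AttA and AttB; 0.0905), the male germline list (20, such as Mst77F and Mst84Da; 0.0905) or chorion proteins (14, such as Cp15 and Cp16; 0.238). The salivary glue and late puff list passed with a window of 1000 bp (exact test, adjusted p = 0.0385). Among non-coding genes, tRNA genes had 14 of 295 (exact test, adjusted p = 0.238), led by tRNA:Tyr-GTA-1-8, tRNA:Gln-TTG-2-1 and tRNA:Lys-TTT-1-1. The tRNA share was 4.75%, 3.73% and 7.80% in the replicates and 3.05% without replicate 1. MicroRNA genes had 9 of 260 (exact test, adjusted p = 0.0539), led by mir-9377, mir-2491 and mir-275, and small nuclear RNA genes, such as snRNA:7SKa and snRNA:7SKb, had 0 of 32 (adjusted p = 0.245). MicroRNA genes passed as lower with a window of 1000 bp (exact test, adjusted p = 0.0168) and among the stronger peaks of the IDR set (adjusted p = 0.0265). The microRNA genes as annotated had a median length of 0.092 kb. Whether their annotated starts are where transcription begins was not tested, so these shares need not describe microRNA promoters.

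At the tagged gene itself, ZnT49B (FBgn0033762; dm6 2R, 12652805 to 12655743, plus strand), no IDR peak lay in the gene or at its TSS. The nearest IDR summit, at 12647181, was 5624 bp away and ranked 3778. The 20 kb on either side held 3 IDR peaks, a density higher than that around 62.9% of protein-coding genes. In the relaxed lists, replicate 1 had a call 166 bp from the gene at rank 3345 and replicate 2 had one 118 bp away at rank 6491, while replicate 3 had none in the gene or at its TSS. The list of zinc transporters and metallothioneins had an IDR peak at 3 of 24 members (12.5%, exact test, adjusted p = 0.893). The replicates gave 25%, 12.5% and 25% (20.8% ± 7.22, SD, n = 3), and the share was 20.8% with a TSS window of 1000 bp, 4.17% without replicate 1, and 0 among genes with no other gene's TSS within 500 bp. Of the members with a peak, ZnT77C (3L, 20493483 to 20493717) had rank 492 (199 ± 41.2 over the replicates, SD, n = 3). The summit counted for foi, a zinc importer, was nearer to the TSS of GstO1.

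Peak density per Mb was 52.7 on X, 49.5 on 2L, 42.7 on 2R, 53.4 on 3L and 46.1 on 3R, but 11.3 on chromosome 4, which held 15 peaks, and Y had none. Over the replicates it was 52.8 ± 3.03 on X and 12.8 ± 2.71 on chromosome 4 (SD, n = 3). Relative to their shares of TSS positions, X (19.1% of peaks against 16.5%) and 3L (23.1% against 19.2%) held more peaks. Chromosomes 2L (18.0% against 19.4%), 2R (16.7% against 20.5%), 4 (0.232% against 0.772%) and Y (0 against 0.477%) held fewer, and 3R was not different (exact binomial, adjusted p = 0.585). In these exact binomial tests the adjusted p was 2.49e-08 for X, 1.10e-14 for 3L, 0.00445 for 2L, 1.10e-14 for 2R, 2.44e-08 for chromosome 4 and 1.77e-13 for Y. Males and females were pooled, so X and Y differ from the other chromosomes in copy number, which the tests do not correct for. The treatment of reads that match several places is also unknown, so absence of peaks from Y is uncertain. The genes with most IDR peaks in their bodies were long ones, kirre (a cell adhesion protein of myoblast fusion) with 28 in 394 kb, lncRNA:CR44357 with 26 in 239 kb and sbb with 21 in 79.1 kb.

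Summits lay in AT-rich sequence. GC content within 100 bp to either side was 34.3% at IDR summits and 34.6% ± 0.462 in the strongest calls of the replicates (SD, n = 3), against 41.9% in the control windows and 42.04% at TSSs without a peak. The last 1000 calls of the replicates were at 41.9% ± 0.410. Of 16 consensus sequences, 6 were more frequent at summits than in the control windows and 5 less frequent. Against windows matched on GC content, 9 were more frequent and 0 less frequent, so several directions depend on the control. More frequent against both were the DRE, found at housekeeping promoters (1.33% of windows, 2.52-fold over the control windows and 1.58-fold over GC-matched ones), Ohler motif 1 (2.78-fold and 4.12-fold), Ohler motif 7 (1.53-fold and 1.53-fold) and a poly-A run (1.42-fold and 1.12-fold). Against the control windows, Ohler motif 1 did not pass without replicate 1 (1.93-fold, exact test, adjusted p = 0.0980) or without replicate 2 (2.21-fold, adjusted p = 0.0533), and was 0.952-fold among the stronger peaks of the IDR set. Ohler motif 7 did not pass in windows reaching 50 bp to either side (1.23-fold, exact test, adjusted p = 0.182) or for TSS peaks against TSSs without a peak (1.07-fold, adjusted p = 0.591). When only peaks at a TSS were set against TSSs without a peak, the DRE (0.598-fold) and Ohler motif 1 (0.435-fold) were less frequent. Summits of TSS peaks lay at a median of −131 bp from the TSS, so the 2 sets of windows may cover different parts of a promoter. Ratios from that comparison therefore do not show whether promoters with a peak hold these sequences less or more often. The GAGA element was 1.07-fold (exact test, adjusted p = 0.378) over the control windows and 2.61-fold (adjusted p = 1.10e-31) over GC-matched ones. Over the control windows it also passed without replicate 2 (1.24-fold, exact test, adjusted p = 0.0229) and in windows reaching 200 bp to either side (1.85-fold, adjusted p = 7.66e-33), and it passed for TSS peaks against TSSs without a peak (1.496-fold, adjusted p = 9.21e-05). The GAGA ratio was below 1 without replicate 1 (0.926-fold) and without replicate 3 (0.956-fold). It was also below 1 in windows reaching 50 bp to either side (0.779-fold) and among the stronger IDR peaks (0.863-fold). None of these values below 1 passed. The metal response element, bound by MTF-1, was less frequent than in the control windows (0.721-fold, exact test, adjusted p = 0.000436) and more frequent than in GC-matched ones (1.41-fold, adjusted p = 0.000220), and did not pass in windows reaching 200 bp to either side (1.03-fold) or for TSS peaks against TSSs without a peak (0.758-fold). The ecdysone receptor inverted repeat was in 2 IDR windows and did not differ (exact test, adjusted p = 0.176), but was less frequent without replicate 1 (adjusted p = 0.0184).

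**Figure D4:**
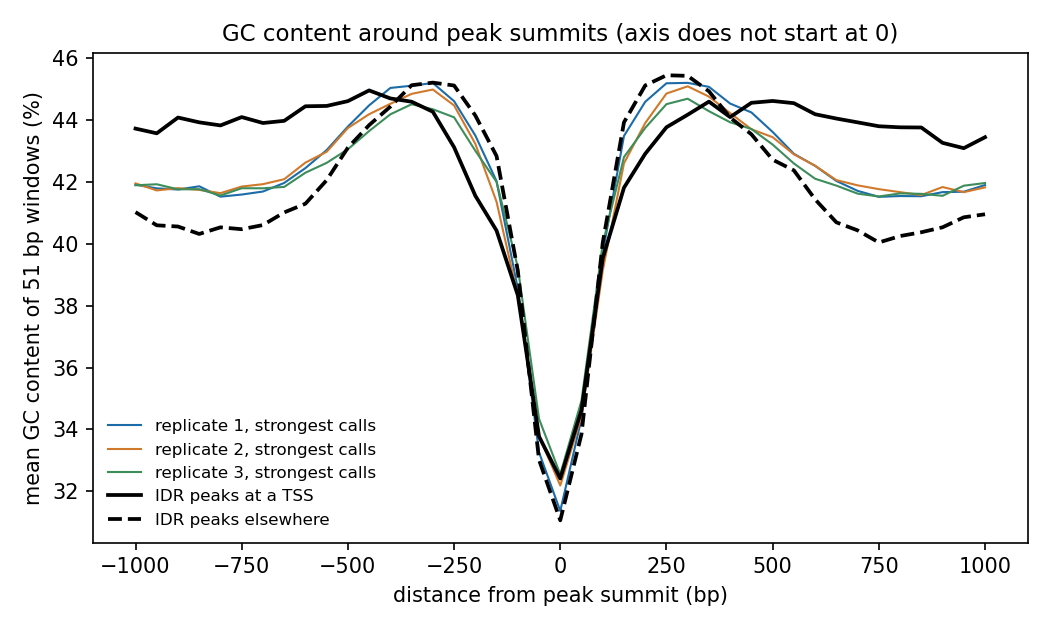
Mean GC content of 51 bp windows (vertical axis, not starting at 0) by distance from the summit (horizontal axis) for the strongest calls of the 3 replicates and for IDR peaks at a TSS and elsewhere. GC content is 32.4% at the summit of TSS peaks and 31.1% at that of other peaks.

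The replicates shared most of their strongest calls. Of the 6469 strongest calls of a replicate, 78.4% ± 0.755 overlapped one of another (SD over 3 pairs), against 3.53% after random placement. Of the IDR peaks, 4534 (70.1%) overlapped such a call in all 3 replicates and 97.4% a call of any rank in all 3. Across IDR peaks, Spearman's rho between the signals of 2 replicates was 0.783 ± 0.0215 (SD over 3 pairs). Peaks are not independent replicates, so no p-value was attached. The IDR peaks are the strongest calls on these same replicates pooled, which favours their overlap and correlation in advance. No random share was computed for the overlap of IDR peaks with the replicates. On build dm3 the IDR set held 5986 peaks, 92.5% of the number on dm6. The relaxed list of replicate 2 was shorter on dm3, with 24114 calls against 29322.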

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

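All alternatives here were chosen before the data were examined. The excess of peaks at a TSS, their higher signal, the number of chromosomes past the test (6), and the number of lists past the test stayed on their side of the threshold or within 1.5 times under every alternative run, and single chromosomes were followed only for X, 2R, 3L and 4. The number of lists was 6 and reached that limit of 1.5 times, with 4 when only gene starts were used and 9 with a TSS window of 1000 bp. The share of calls recurring between replicates was 81.2% with the strongest 3234 calls, 71.8% with the strongest 12938, 76.8% with 50% overlap and 70.1% with summits within 100 bp, and ran from 77.7% to 79.2% with a replicate left out. Spearman's rho ran from 0.765 to 0.807 with a replicate left out. The fall in TSS share with rank was 23.8 percentage points with a 250 bp window and 33.8 with 1000 bp. The number of consensus sequences past the test was 11, but 7 with windows reaching 200 bp to either side and 6 for TSS peaks against TSSs without a peak, and both of these numbers include some that were not among the 11. The tagged gene had 1 call in the relaxed list of replicate 1 and 1 in that of replicate 2. The dm3 set was 98.6% of the dm6 set among peaks above the dm6 median signal. Directions reversed for consensus sequences, and the cause was not tested. Only turns where the original or the alternative value passed the test are listed, and others that crossed 1 without passing in either are not. Against GC-matched windows these were the E-boxes CACGTG (1.11-fold) and CAGCTG (1.33-fold), the metal response element (1.41-fold), the CTCF site (1.59-fold) and the CA repeat (1.29-fold). With the wider windows they were CAGCTG (1.07-fold), the metal response element (1.03-fold), AP-1 (1.01-fold) and the CA repeat (1.17-fold). For TSS peaks against other TSSs they were the DRE (0.598-fold), Ohler motifs 1 (0.435-fold) and 6 (0.607-fold), the TATA box (0.999-fold), CRE (2.66-fold) and the CA repeat (1.14-fold). In the stronger part of the IDR set Ohler motif 1 turned (0.952-fold). Of the other values for single lists, consensus sequences and chromosomes, 27 lost their call and 12 gained one. The other 292 stayed on the same side of the threshold, though many of their values moved, or were shares of chromosomes on dm3, compared without a test. The strongest 6469 pooled calls are the IDR set itself, so that alternative tested nothing. The tagged gene was not run on dm3. No paired analysis was possible because there was 1 group. Depth is unknown, so what it limits could not be measured.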

Other observations

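The gene families, the 8-mers and their tests below were chosen after the main results had been seen. What each technical source would predict was written before its test was run, except where stated. Protein-coding genes were grouped by the letters that open their symbols, and 38 families had at least 15 members. By Fisher exact test with adjustment over the families, 3 had peaks at the TSS of more members than other protein-coding genes and 8 at fewer. Besides both ribosomal protein families, the higher one was Atg, the autophagy genes, with 8 of 20 (40%, exact test, adjusted p = 0.0434; 43.3% ± 2.89 over the replicates, SD, n = 3). These were Atg2, Atg4b, Atg7, Atg8a, Atg9, Atg12, Atg17 and Atg18a, named after their values were seen. The summits counted for Atg7, Atg12 and Atg17 were nearer to the TSS of another gene, and the planned cell death and autophagy list was at 20% (exact test, adjusted p = 0.590) among genes with no other gene's TSS within 500 bp. Peroxisome biogenesis genes of the Pex family had 6 of 15 (exact test, adjusted p = 0.0944) and did not pass.

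Beyond the histones, receptors and cuticle families that the lists already cover, the families with fewer peaks were the ionotropic receptors Ir (0 of 60, exact test, adjusted p = 0.000184), the odorant-binding proteins Obp (2 of 51, adjusted p = 0.0345), the sodium channels ppk (0 of 29, adjusted p = 0.0390) and the cytochromes P450 Cyp (5 of 85, adjusted p = 0.0168). Mitochondrial ribosomal proteins did not stand apart as the cytoplasmic ones did, with 8 of 26 for mRpS (exact test, adjusted p = 0.174) and 10 of 47 for mRpL (adjusted p = 0.674), and no test of the difference between the families was run.

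Short sequences containing CAGTG were frequent beside summits. The 10 leading 8-mers chosen on X, 2L and 3L all contained it, and on 2R and 3R, 18.6% of 2557 IDR windows held at least 1 of them against 3.70% of GC-matched windows, a ratio of 5.02 (95% interval 4.45 to 5.66). CACTGAGA was in 4.50% against 0.548%. Base composition is argued against, since the highest of 20 shuffles that keep dinucleotide counts reached 3.44%. So is a single library, since the lowest of the 3 replicates' lower bounds was 3.65. Of 272 IDR windows with no soft-masked base, 42 held an 8-mer, a ratio of 3.89 with a lower bound of 2.66. That argues against repeats in those windows only. The rest of the 2557 windows hold soft-masked bases, so repeats stay open there. The pattern had been seen on all chromosomes before this split, so a sequence-specific factor at these sites is only a hypothesis, and no biological explanation was tested.

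The matches on 2R and 3R were fewer at the summit itself than beside it. There were 299 between −100 and −50 bp and 319 between 50 and 100 bp, but 116 and 127 in the central bins of 50 bp and 68 and 55 in the outermost, 250 to 300 bp away. The share of windows with an 8-mer was 17.4% ± 0.926 in the strongest 6469 calls of the replicates (SD, n = 3) and 7.48% ± 0.717 in their last 6469.

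The concentration of peaks at TSSs was set against technical sources. Windows matched on GC content lay at a TSS in 12.8% of cases, below the lower bound of 34.1% of the observed share, which argues against promoter base composition. Of tRNA genes, 4.75% (3.05% without replicate 1) had a peak against 17.0% of protein-coding genes (Fisher exact, p = 3.85e-10) and 7.30% of other non-coding genes (adjusted p = 0.238). By the prediction written beforehand this would have counted against recovery from RNA polymerase III or highly transcribed genes, but after the values were known it was judged open, because tRNA genes are multicopy and say nothing of RNA polymerase II genes such as those of ribosomal proteins, at 61.3%. Without a sample lacking the fusion protein among those analysed here, recovery that depends on open chromatin or on the antibody cannot be separated from recovery of the fusion protein.

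Low GC content may account for part of the near absence of peaks from coding exons, since windows matched on GC content were in coding exons in 4.80% of cases against 17.5% of all windows. It is not the whole of it, as IDR summits on the chromosome arms were at 0.434% with an upper bound of 0.626%. The cause of the remainder was not tested.

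A raised peak density from extra copies of the tagged locus was not seen, with ZnT49B at percentile 62.9 where a value above 95 had been set beforehand. That value rests on 3 IDR peaks. In the relaxed lists the percentile was higher but also below 95, at 81.9, 84.9 and 75.1 in replicates 1, 2 and 3. A count of peaks does not measure signal, so raised signal from extra copies was not tested.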
